A study of Caenorhabditis elegans with 14 samples.

How the data were processed

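The series holds 14 sequencing samples from C. elegans larvae of the wild-type N2 strain, of which 10 are chromatin immunoprecipitations (ChIP) of RNA polymerase II and 4 are input chromatin. In ChIP, DNA crosslinked to a protein is recovered with an antibody and sequenced, so that read density along a gene measures how much of the protein was bound there. Per the labels' protocols, embryos hatched without food and stopped in L1 arrest, a starvation-induced developmental arrest of the first larval stage, and larvae were fixed with formaldehyde after 6 hr or 12 hr. Recovery samples were fed HB101 bacteria after 12 hr of arrest and fixed 1 hr later. Antibodies named S2, 4H8 and 8WG16 were used. All 3 bind the C-terminal domain of the largest polymerase subunit. The catalogue number in the labels identifies S2 as an antibody to the domain phosphorylated at serine 2, a mark of elongating polymerase, and 8WG16 is known to bind mostly the unphosphorylated form.

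The authors deposited read densities in RPKM (reads per kilobase of sequence, scaled to sequencing depth) for each gene model and for a 200 bp window over the most upstream annotated transcription start site (TSS), per the file headers. They also deposited fold enrichment over input, a ratio whose denominator was the input density or the median input density where that was higher, per the file headers. Their 5' bias was the ratio of TSS enrichment to gene enrichment, per the file headers. Gene coordinates were those of the WS190 annotation, with start and end positions counted from 1. The aligner and its settings are not given in the sources used here. The tables hold 1 column for the pooled input and 1 column for the S2 samples at 6 hr, carrying the title of replicate 1, so that 9 ChIP columns were used, each called a library. Whether the 6 hr column holds both samples is not stated. The input column is taken as pooled because it names no single sample and its depth exceeds that of any ChIP library.

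RPKM keeps no depth by itself, but low TSS densities were whole multiples of a step that corresponds to 1 read in 200 bp, and this step gave the number of reads behind each library. Depth was 11906000 reads for the pooled input and between 1323000 and 5863000 for the ChIP libraries. With these depths, between 93.8% and 99.4% of gene densities and between 89.4% and 90.2% of TSS densities came out as whole reads within 0.1 read. The remaining TSS windows had steps of a shorter window. Across the ChIP libraries the median gene model held 26 to 105 reads and the median TSS window 2 to 8 reads. A TSS window with 3 reads corresponded to between 2.56 and 11.3 RPKM in the ChIP libraries, so differences below that density could not be detected. Reads were not identified as single molecules, and these limits cover counting error only.

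Values were analysed as log2(RPKM + 5). Changes are log2 ratios on that scale, which understates the change of genes of low density. For each library a 5' bias was computed as the log2 ratio of TSS density + 5 to gene density + 5, in gene models of at least 1000 bp. Genes entered a fit where their mean density over the libraries of the fit was at least 10 RPKM, close to the median of the input, 10.96 RPKM for gene models and 10.08 RPKM for TSS windows. For 5' bias it was enough that either the gene or the TSS density reached this, so the other could be lower. Tests used limma (lmFit, then eBayes with a mean-variance trend, two-sided) in R 4.3.3 with limma 3.58.1, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

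Recovery was compared with 12 hr of arrest in a fit of the 8 libraries from these states, with antibody as a term. This averages the effect over libraries, so that 4H8, with 2 per state, weighs as much as S2 and 8WG16 together. A fit of all 9 ChIP libraries in 7 groups gave the 4H8 comparison (2 libraries per state), the S2 comparison of 12 hr with 6 hr, and the difference between 4H8 and S2 in their response to feeding. S2 and 8WG16 had 1 library per state, and in the fit of 9 libraries such a library was assumed to vary like the 4H8 replicates. The fit had been planned with 10 libraries. A planned exact permutation test of ChIP against input libraries could not be run on a single pooled input column, and the values are given without a test. The series description calls the pairs of 4H8 samples biological replicates. Whether different antibodies were used on the same chromatin is not stated, so the spread between samples in the averaged fit may be partly technical. Its p-values also rest on spread pooled over genes, since eBayes draws each gene's variance towards a trend. This prior counted for 43.77 degrees of freedom for TSS density, 16.23 for 5' bias and 4.34 for gene density, against 4 from a gene's own residuals. In the fit of 9 libraries these were 43.78, 17.99 and 4.26, against 2. Small p-values for TSS density and 5' bias thus rest mostly on the pooled spread.

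The labels place each 12 hr arrest library and a recovery library of the same antibody on a shared flow cell, which gives 4 pairs. Deviations of the paired 4H8 libraries from their group means correlated across genes at 0.334 for gene density, 0.229 for TSS density and 0.17 for 5' bias. Every flow cell of these pairs held both states. The fits without the pair as a replicate block were set as the main ones before the data were examined, and the fits with the block are given where they change a count by over 1.5 times. The replicate libraries were compared before they were averaged. Log2 gene densities correlated at 0.921 in arrest and 0.92 in recovery, and read counts differed by more than sampling noise (chi-square over degrees of freedom of 3.52 and 9.92).

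A set of 30 gene lists was fixed by symbol before the data were examined. They covered ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, ribosome biogenesis, the mitochondrial ribosome, oxidative phosphorylation, the vacuolar ATPase, the proteasome, heat shock proteins and chaperones, DAF-16 stress targets, fasting metabolism, lipid synthesis, vitellogenins, collagens and cuticle, histones, cell cycle and DNA replication, insulin signalling, muscle, intestine, neurons, germline, sperm, chemoreceptors, immune lectins and lysozymes, detoxification, splicing, the transcription machinery, transcription factors of the bZIP, bHLH and immediate early kinds, the tubulin and actin cytoskeleton, and heterochronic genes. Lists were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01 and again with a correlation estimated from the residuals. With the estimated correlation no list passed in any fit. Symbols came from the coordinate table and, for 19707 of 20315 genes, from RefSeq names on WBcel235, used for names only. WS190 symbols are printed as in the coordinate table. Because lists were matched by symbol alone, a list can hold genes of another function. One is rpa-0, which encodes a ribosomal protein but matches the cell cycle list. Of the genes, 20314 had coordinates and 11548 a public symbol.

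Named genes followed a rule fixed before the data were examined. It took the 10 highest and 10 lowest changes among genes past the threshold that have a public symbol and moved the same way in every pair, filled to 5 per direction by the smallest unadjusted p where fewer passed. It further took the 2 members of each list with the highest density and the 2 with the largest moderated statistic, and a panel of 63 genes. Together these made 366 genes. For named genes, a neighbouring gene model within 500 bp, or an overlapping one, is given where its reads could fall into the TSS window or the gene model, because the densities do not use strand. Annotated 5' ends are often trans-splice sites in C. elegans, so the TSS window need not hold the site of initiation. Genes of repeated families such as histones could share reads with close copies.

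The fit of 8 libraries was tested on simulated data with 200 changed genes. At a 2-fold change it recovered 72% of the genes for gene density, 51% for TSS density and 100% for 5' bias, and at a 4-fold change 100% for each. False calls were 14 of 186 among 7444 genes for gene density, 6 of 157 among 6987 for TSS density and 4 of 204 among 7775 for 5' bias. Gene and TSS densities of the changed genes were moved in opposite directions, so that their 5' bias moved by more than the named fold. The simulated spread between libraries was shared by the gene and TSS density of a gene, so it largely cancelled in the 5' bias. No difference in background or TSS enrichment between libraries of an antibody was simulated, so these shares need not hold for the real libraries. Alternatives planned before the data were examined were a pseudocount of 1 or 20 RPKM, no density filter or a filter of 20 RPKM, quantile normalization, the authors' fold enrichment over input (pseudocount 0.5), the replicate block, the 4H8 libraries alone, gene models of any length, robust eBayes without the trend, and leaving out each library. Added after seeing the data were limma-voom on the recovered reads, scaling on chemoreceptor genes, genes at least 500 bp from another gene model, leaving out the 8WG16 libraries, gene models of at least 200 bp, and genes at or above the input density. For the scaling on chemoreceptor genes, each library was divided by its median density over 1283 chemoreceptor genes, taken as background. These medians differed between replicates of a state, so the scaling can also end a call by adding spread.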

Results

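RNA polymerase II was mapped by ChIP-seq in L1-arrested larvae of C. elegans and in larvae 1 hr after feeding. L1 arrest is the state in which larvae that hatch without food wait, without growing, until they are fed. The comparisons ask where polymerase sits on genes during starvation and how this changes within 1 hr of feeding. At 6 hr of arrest there was 1 S2 column for 2 samples. At 12 hr of arrest and in recovery there were S2 (n = 1), 4H8 (n = 2) and 8WG16 (n = 1). Depth was 2593000 reads for S2 at 6 hr and 4273000 for S2 at 12 hr. The arrest libraries of 4H8 had 2800000 and 4643000 reads, and that of 8WG16 had 1689000. In recovery S2 had 3071000 reads, 4H8 had 4500000 and 5863000, and 8WG16 had 1323000. The single input column, taken as the pool of the 4 input samples, had 11906000 reads. Densities are in RPKM, and changes are log2 ratios ± standard error of the limma fit unless given as mean ± SD.

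Within 1 hr of feeding, polymerase density fell most at acs-2 and gei-7 among genes with a public symbol that moved the same way in every pair. It rose at asp-1 and at all 80 ribosomal protein genes tested (68 of them after scaling on chemoreceptor genes). The acyl-CoA synthetase gene acs-2 (V:15567368-15569863), which serves fatty acid oxidation, fell by 5.39 ± 0.20 (adjusted p = 5.46e-06), from 1359 ± 523 to 24.7 ± 2.31 RPKM with 4H8 (mean ± SD, n = 2 per state), below its input density of 28.6. The isocitrate lyase gene of the glyoxylate cycle, gei-7 (V:724209-728105), fell by 4.38 ± 0.17 (adjusted p = 5.46e-06), from 924 ± 145 to 36.3 ± 3.32 RPKM with an input of 29.4. The aspartic protease gene asp-1 (V:19049422-19050789) rose by 2.97 ± 0.24 (adjusted p = 7.07e-05), from 51.2 ± 20.7 to 546 ± 84.1 RPKM with an input of 54.9. Across antibodies, 2743 of 7214 genes passed the test, 1653 higher and 1090 lower in recovery.

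Among the genes with the largest falls, the alcohol dehydrogenase gene sodh-1 (V:11888213-11889611) went from 1086 ± 232 to 90.3 ± 17.6 RPKM with 4H8, a change of -3.61 ± 0.18 (adjusted p = 9.86e-06). For dap-1 (I:7492041-7492927) the change was -3.45 ± 0.17, from 404 ± 2.95 to 35.2 ± 5.61 RPKM. Changes were -2.64 for acer-1, -2.48 for sodh-2, -2.46 for the steroid dehydrogenase family gene stdh-1, -2.42 for the fatty acid and retinol binding protein gene far-7, -2.37 for the hydroxyacyl-CoA dehydrogenase gene hacd-1 and -2.32 for the calponin gene cpn-3. Among those with the largest rises were tct-1 (I:10569097-10570019), encoding the translationally controlled tumour protein, at 2.93 ± 0.22, from 90.6 ± 5.55 to 643 ± 253 RPKM with 4H8. The tyrosine catabolism gene hpd-1 (III:10535410-10537565) rose by 2.64 ± 0.16, from 14.3 ± 0.93 to 117 ± 39.9 RPKM, and the cathepsin B family gene cpr-4 by 2.52 ± 0.17, from 32 ± 4.38 to 249 ± 2.48 RPKM. The ribosomal protein genes rps-16 and rps-6 rose by 2.50 and 2.47. The other 4 of the 10 highest lay in or beside ribosomal protein genes. These were mir-353 (2.97) inside rpl-24.1, nbs-1 (2.60) 92 bp from rpl-41, nssp-7 (2.49) 473 bp from rpl-14 and the insulin-like gene ins-17 (2.46) 696 bp from rps-1. The gene tct-1 lay 85 bp from rpa-0, which also encodes a ribosomal protein.

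Of the lists of protein synthesis, ribosomal proteins and translation factors had the largest shares of members called. All 80 ribosomal protein genes tested passed, all higher in recovery (80 when adjusted over the list alone), with a median change of 1.84 (camera adjusted p = 1.82e-32, and adjusted p = 0.664 with an estimated correlation). After scaling on chemoreceptor genes 68 passed (median 1.41). Examples were rpl-26 at 2.32, rla-1 at 2.21, rps-12 at 2.23, rps-3 at 2.10, rpl-3 at 2.07 and rpl-2 at 1.77. Of 36 translation factors, 31 were higher and 1 lower (31 and 1 adjusted over the list alone). Their median was 0.66 (adjusted p = 1.11e-08, and adjusted p = 0.664 with an estimated correlation). The elongation factor gene eft-3 rose by 2.00 ± 0.17 from 121 ± 9.59 to 540 ± 135 RPKM with 4H8, eft-4 by 2.05, eft-2 by 1.79 and the initiation factor gene ifg-1 by 0.75. Of 27 aminoacyl-tRNA synthetases, which charge tRNAs, 14 were higher and 0 lower (18 and 0 adjusted over the list alone). Their median was 0.44 (adjusted p = 0.000361, and adjusted p = 0.664 with an estimated correlation). Examples were ers-2 at 0.65 and lrs-1 at 0.64. Of 30 ribosome biogenesis genes, 13 were higher and 1 lower (14 and 1 adjusted over the list alone). Their median was 0.26, and -0.075 after scaling on chemoreceptor genes (adjusted p = 0.00234, and adjusted p = 0.664 with an estimated correlation). They included the fibrillarin gene fib-1 at 2.08 ± 0.15 (63.4 ± 9.8 to 286 ± 33.8 RPKM) and nol-56 at 1.82. After that scaling 7 translation factors, 0 aminoacyl-tRNA synthetases and 5 ribosome biogenesis genes were called higher. Of the members called higher before it, 0 of 80, 0 of 31, 2 of 14 and 1 of 13 had a mean density below their input density. Heat shock proteins and chaperones had 19 higher and 3 lower of 39 (19 and 4 adjusted over the list alone). Their median was 0.27, and -0.087 after scaling on chemoreceptor genes (adjusted p = 0.027, and adjusted p = 0.726 with an estimated correlation). The constitutive chaperone gene hsp-1 rose by 2.15 ± 0.18 from 97.6 ± 4.59 to 477 ± 115 RPKM, hsp-12.3 by 1.81 and daf-21, the HSP90 gene, by 1.41, while the endoplasmic reticulum chaperone gene hsp-4 rose by 0.41 (0.065 after that scaling, adjusted p = 0.84).

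The fasting metabolism list went lower by camera, with members in both directions. In it 17 of 43 were lower, 10 higher and 16 not called (17 and 11 adjusted over the list alone). Their median was -0.16 (adjusted p = 0.0177, and adjusted p = 0.664 with an estimated correlation). The list was led by acs-2 and gei-7. Of 25 genes in the list of targets of DAF-16, the FOXO factor of insulin signalling, 12 were lower and 4 higher (12 and 5 adjusted over the list alone). Their median was -0.21 (adjusted p = 0.0148, and adjusted p = 0.664 with an estimated correlation). The linker histone gene hil-1 was at -2.14 ± 0.09 and the metallothionein genes mtl-1 and mtl-2 were at -1.09 and 0.49. The list does not separate genes that DAF-16 raises from genes that it lowers, so its direction does not give that of DAF-16 activity. Of 22 transcription factors of the bZIP, bHLH and immediate early kinds, 7 were lower and 0 higher (5 and 0 adjusted over the list alone). Their median was -0.23 (adjusted p = 0.0213, and adjusted p = 0.664 with an estimated correlation, adjusted p = 0.057 after scaling on chemoreceptor genes). Among them the bZIP genes zip-2, zip-1 and xbp-1 were at -1.38, -0.59 and -0.46, and each passed. In insulin signalling 7 of 25 genes were higher and 7 lower (7 and 7 adjusted over the list alone). Their median was 0.067, and -0.25 after scaling on chemoreceptor genes (camera lower, adjusted p = 0.853). The insulin-like peptide gene daf-28 rose by 1.63 ± 0.13, while the receptor gene daf-2 was at -0.74, daf-16 at -0.48 and ins-27 at -0.98, each past the threshold.

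The collagen, germline, sperm, immune and intestinal lists passed as higher, whereas the muscle, neuronal and chemoreceptor lists did not pass, and in all of the 5 but the intestinal list most members called higher had densities below the input. Of 127 collagen and cuticle genes, 70 were higher and 3 lower (81 and 5 adjusted over the list alone). Their median was 0.45 (adjusted p = 8.22e-07, and adjusted p = 0.664 with an estimated correlation), and 53 of the 70 had a mean density below input. After scaling on chemoreceptor genes 6 were higher and 4 lower. Examples were col-138 at 1.93, col-19 at 0.72 and col-98 at -1.52. Germline genes had 21 of 37 higher and 2 lower (22 and 2 adjusted over the list alone). Their median was 0.32, and -0.006 after scaling on chemoreceptor genes (adjusted p = 0.00347, and adjusted p = 0.664 with an estimated correlation). Of these 21, 15 were below input. Examples were pgl-1 at 0.89, cgh-1 at 0.82 and cpg-8 at -1.89. Sperm genes had 13 of 34 higher and 0 lower (13 and 0 adjusted over the list alone). Their median was 0.49 (adjusted p = 0.00126, and adjusted p = 0.664 with an estimated correlation). Of these 13, 9 were below input. Examples were gsp-4 at 1.11 and spe-26 at 0.78. Immune lectins and lysozymes had 30 of 79 higher and 9 lower (38 and 9 adjusted over the list alone). Their median was 0.41 (adjusted p = 0.0277, and adjusted p = 0.736 with an estimated correlation, and adjusted p = 0.0613 with the authors' fold enrichment). Of these 30, 18 were below input. The lectin genes clec-221, clec-1 and clec-178 were at -1.89, -0.62 and 0.62, and the F-box gene fbxa-24, which the list also holds, was at -2.11 ± 0.11. Intestinal genes had 18 of 33 higher and 4 lower (20 and 5 adjusted over the list alone). Their median was 0.49 (adjusted p = 0.00194, and adjusted p = 0.664 with an estimated correlation), and only 4 of those 18 were below input. The saposin-like genes spp-23 and spp-17 rose by 2.46 and 1.79, the cathepsin B gene cpr-1 by 1.22, the peptide transporter gene opt-2 by 0.86 and vha-6 by 0.79, and elt-2, the main intestinal GATA factor, was at 0.13 (adjusted p = 0.299).

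The other lists did not pass camera at an adjusted p under 0.05. Higher and lower members were 10 and 4 of 52 for the mitochondrial ribosome (8 and 4 adjusted over the list alone). Their median was 0.10, against -0.033 under quantile normalization and -0.24 after scaling on chemoreceptor genes (adjusted p = 0.897). Examples were mrpl-53 at -1.70 and mrpl-50, which overlaps cct-2, at 1.10. Oxidative phosphorylation had 7 and 4 of 40 (6 and 3 adjusted over the list alone). Their median was 0.12, against -0.05 under quantile normalization and -0.24 after scaling on chemoreceptor genes (adjusted p = 0.723). The vacuolar ATPase had 1 and 3 of 19 (1 and 3 adjusted over the list alone). Their median was -0.10 (adjusted p = 0.224). The proteasome had 2 and 1 of 32 (0 and 0 adjusted over the list alone). Their median was 0.13, and -0.26 after scaling on chemoreceptor genes (adjusted p = 0.853). Lipid synthesis had 8 and 6 of 28 (10 and 6 adjusted over the list alone). Their median was 0.14, and -0.25 after scaling on chemoreceptor genes (adjusted p = 0.73). Examples were the fatty acid synthase gene fasn-1 at 0.76 and the desaturase genes fat-2, fat-6 and fat-5 at 1.02, -0.98 and -1.35. Histones had 13 and 7 of 31 (14 and 8 adjusted over the list alone). Their median was 0.39 (adjusted p = 0.723). Examples were his-24 at -1.08 and hil-7 at -1.59. Cell cycle and DNA replication had 18 and 3 of 49 (19 and 3 adjusted over the list alone). Their median was 0.22, and -0.11 after scaling on chemoreceptor genes (adjusted p = 0.0902), and 11 of the 18 were below input. Of these genes cdc-6 rose by 0.73 and cdk-1 by 0.44, and cyd-1 was at 0.13 (adjusted p = 0.275). Muscle genes had 4 and 7 of 37 (4 and 6 adjusted over the list alone). Their median was 0.012 (camera lower, adjusted p = 0.217). It was -0.198 (adjusted p = 0.0471) under quantile normalization and -0.40 after scaling on chemoreceptor genes. Examples were the myosin genes myo-3 at -0.95 and unc-54 at 0.11 (adjusted p = 0.601).

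Neuronal genes had 15 higher and 6 lower of 63 (15 and 4 adjusted over the list alone). Their median was 0.19, and -0.14 after scaling on chemoreceptor genes (adjusted p = 0.279). Of these 15, 11 were below input. Examples were the neuropeptide genes nlp-4 at 0.92 and flp-28 at -0.71. Chemoreceptors had 8 and 3 of 44 (6 and 3 adjusted over the list alone). Their median was 0.18, and -0.16 after scaling on these genes (adjusted p = 0.408). Examples were srb-7 at 2.12, which lies 1454 bp from rps-14, and srd-4 at -1.02. Detoxification genes had 10 and 5 of 23 (11 and 5 adjusted over the list alone). Their median was 0.29, and -0.12 after scaling on chemoreceptor genes (adjusted p = 0.267). Examples were the glucuronosyltransferase genes ugt-63 at 1.44 and ugt-46 at 1.19. Splicing genes had 10 and 2 of 32 (10 and 2 adjusted over the list alone). Their median was 0.24, and -0.16 after scaling on chemoreceptor genes (adjusted p = 0.0873). Examples were snr-2 at 1.09 and rsp-7 at 0.85. The transcription machinery had 5 and 7 of 41 (5 and 7 adjusted over the list alone). Their median was 0.11 (mean -0.003, median -0.237 after scaling on chemoreceptor genes, camera lower, adjusted p = 0.853). Examples were the TFIID subunit gene taf-10 at -1.43 and ama-1, which encodes the largest polymerase subunit, at 0.44. Tubulin and actin cytoskeleton genes had 6 and 0 of 22 (5 and 0 adjusted over the list alone). Their median was 0.14, and -0.21 after scaling on chemoreceptor genes (adjusted p = 0.448). Examples were tbb-2 at 0.55 and pfn-1 at 0.49. Heterochronic genes, which time larval stages, had 0 and 2 of 9 (0 and 1 adjusted over the list alone). Their median was -0.085 (adjusted p = 0.267). Examples were lin-28 at -0.68 and lin-14 at -0.35 (adjusted p = 0.0745). Among vitellogenins vit-6 alone was dense enough to test, at 0.67, and its mean density was below input.

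Gene counts in this comparison moved with the scaling. Of the 1653 higher genes, 654 had a mean density below their input, where the median change over 2513 tested genes was 0.204, against -0.005 over the 4701 genes at or above input. The median of all genes was 0.083, against -0.013 under quantile normalization and -0.26 after scaling on chemoreceptor genes. In that order the higher and lower calls were 1653 and 1090, 1239 and 1501, and 381 and 1626. Of the 149 tested genes that the naming rule gives for this comparison, 73 passed as higher and 41 as lower, and after scaling on chemoreceptor genes 41 of the 73 and 38 of the 41 still passed. Of the 73, 32 no longer passed, among them ama-1 (0.057, adjusted p = 0.898), ifg-1 (0.35, adjusted p = 0.447), fasn-1 (0.37, adjusted p = 0.408), cgh-1 (0.41, adjusted p = 0.407), ers-2 (0.31, adjusted p = 0.298), lrs-1 (0.33, adjusted p = 0.187), snr-2 (0.69, adjusted p = 0.11), cdc-6 (0.41, adjusted p = 0.115), fat-2 (0.63, adjusted p = 0.134) and vha-6 (0.46, adjusted p = 0.0754). Nor did cdk-1 (0.12, adjusted p = 0.678), tbb-2 (0.12, adjusted p = 0.857), pfn-1 (0.14, adjusted p = 0.711), mtl-2 (0.17, adjusted p = 0.54), rsp-7 (0.47, adjusted p = 0.259), nlp-4 (0.48, adjusted p = 0.389), clec-178 (0.21, adjusted p = 0.691), mrpl-50 (0.69, adjusted p = 0.139), vit-6 (0.35, adjusted p = 0.165) and col-19 (0.39, adjusted p = 0.146). Of these 32, 3 were then below 0, nuo-5 and pas-4 among them. Those of the 41 that no longer passed were gpd-2, gpd-3 and xbp-1, each with a larger fall than before. Without the S2 library of arrest 1784 genes passed, and without the S2 library of recovery 1765.

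**Figure D1:**
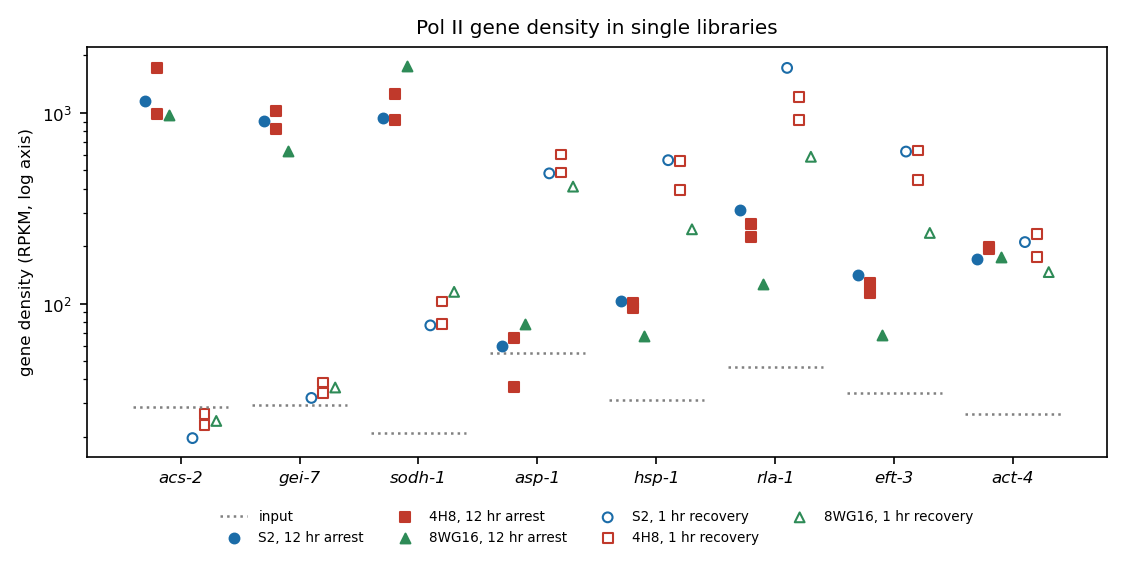
Gene density in RPKM on a log axis for 8 genes in the ChIP libraries of 12 hr arrest and 1 hr recovery, by antibody, 1 point per library, with the pooled input as a dotted line. The genes acs-2, gei-7 and sodh-1 fell in recovery, by log2 changes of -5.39, -4.38 and -3.61, and asp-1, hsp-1, rla-1 and eft-3 rose, by 2.97, 2.15, 2.21 and 2.00, whereas act-4 was at 0.04 (adjusted p = 0.877; -0.51 under quantile normalization and -0.41 after scaling on chemoreceptor genes).

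**Figure D2:**
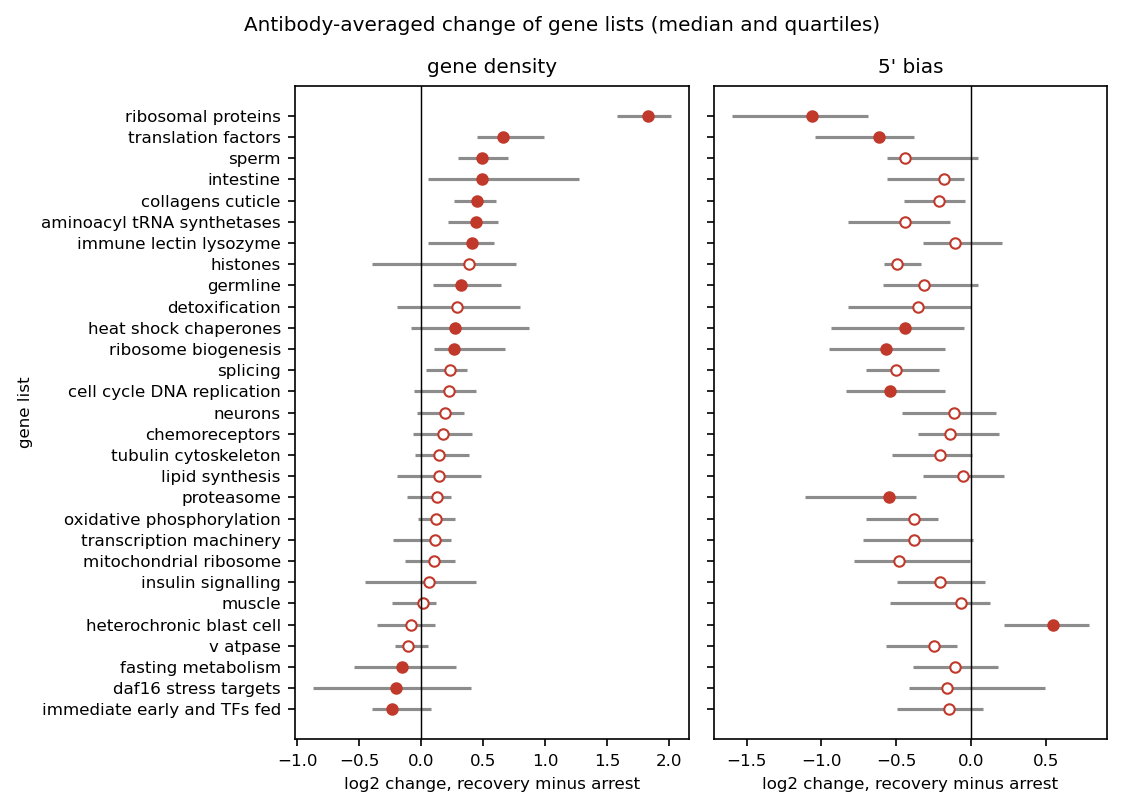
Median (points) and quartiles (bars) of the log2 change from 12 hr arrest to 1 hr recovery over each gene list, for gene density and 5' bias in the fit of 8 libraries, with filled points where camera gave an adjusted p under 0.05. Ribosomal proteins stood highest for gene density (1.84) and lowest for 5' bias (-1.06), and the positive gene density medians of 0.323 or less went below 0 after scaling on chemoreceptor genes.

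At transcription start sites the commoner direction on feeding was down. TSS density fell at 1480 and rose at 476 of 6808 genes (median -0.152), and with no filter on density it fell at 505 and rose at 164 of 20315 (median 0.015). Among the deepest falls were those at acs-2 (-4.79 ± 0.25, adjusted p = 1.32e-20), dap-1 (-3.50), sodh-1 (a ratio of 0.12), gei-7 (-2.85), cpn-3 (-2.63), acer-1 (-2.42) and hil-1 (-2.42), all of which fell in gene density too. The start of lsm-5, an LSm RNA-binding protein gene, lies 68 bp from acs-2 and went from 421 ± 102 to 9.62 ± 2.81 RPKM with 4H8 (-4.76 ± 0.25). The chemoreceptor gene srh-2 (-2.77, from 437 ± 23.7 to 53.1 ± 5.1 RPKM) and fbxb-72 (-2.46) lie 3543 and 380 bp from gei-7. Among the largest rises were pst-2 (3.00, 311 bp from rps-12), ins-17 (2.92, 696 bp from rps-1), inx-7 (2.87, 357 bp from rps-25), suf-1 (2.71, 265 bp from rpl-26), nssp-7 (2.61, 473 bp from rpl-14) and mir-354 (2.54, inside rps-20). The gene rbm-3.1 (2.79) lies 224 bp from rbm-3.2. Away from those, asp-1 rose by 2.52 from 13.8 ± 1.82 to 102 ± 9 RPKM, spp-23 by 2.52 and srab-3 by 2.43, the last of these 262 bp from ugt-63.

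Ribosomal protein genes rose at their starts, with 66 higher and 5 lower of 78 (67 and 5 adjusted over the list alone). Their median was 1.25 (adjusted p = 2e-32, and adjusted p = 0.264 with an estimated correlation). Examples were rpl-25.1 at 2.13 and rps-16 at 2.06. One of the 5 that fell was rpl-7A, whose TSS density with 4H8 went from 727 ± 57.1 to 381 ± 52.7 RPKM (-1.17) while its gene density went from 69.6 ± 8.61 to 274 ± 45.7. Of 23 proteasome genes, 12 were lower and 0 higher at their starts, and 11 were not called (14 lower and 0 higher adjusted over the list alone). Their median was -0.77 (adjusted p = 0.00274, and adjusted p = 0.35 with an estimated correlation). Examples were rpn-5 (-2.34 ± 0.32), rpn-9 (-1.95) and rpn-2 (-1.38). With 4H8 alone, 7 proteasome genes of 24 were lower and 0 higher (camera adjusted p = 0.0642). Intestinal genes had 7 higher and 2 lower of 24 (8 and 2 adjusted over the list alone). Their median was 0.22, and -0.083 after scaling on chemoreceptor genes (adjusted p = 0.00274, and adjusted p = 0.264 with an estimated correlation). DAF-16 stress targets had 5 lower and 0 higher of 15 (6 and 0 adjusted over the list alone). Their median was -0.53 (adjusted p = 0.0254, and adjusted p = 0.35 with an estimated correlation). Fasting metabolism had 13 lower and 2 higher of 40 (14 and 2 adjusted over the list alone). Their median was -0.32 (adjusted p = 0.045, and adjusted p = 0.35 with an estimated correlation). The list did not pass under quantile normalization (median -0.27, adjusted p = 0.093) or with the authors' fold enrichment (median -0.28, adjusted p = 0.0572). The trehalase gene tre-1 was at -1.79. Histones had 10 lower and 0 higher of 32 (12 and 0 adjusted over the list alone). Their median was -0.50 (adjusted p = 0.0292, and adjusted p = 0.479 with an estimated correlation, adjusted p = 0.234 under quantile normalization and adjusted p = 0.0557 after scaling on chemoreceptor genes). Examples were htz-1 at -1.51 and his-24 at -1.14. Collagens passed camera as higher than other genes, although 4 were higher and 8 lower of 85 (3 and 5 adjusted over the list alone). Their median was 0.19, and -0.13 after scaling on chemoreceptor genes (adjusted p = 0.0249, and adjusted p = 0.479 with an estimated correlation). Sperm genes had 2 higher and 1 lower of 14 (2 and 1 adjusted over the list alone). Their median was 0.42 (adjusted p = 0.045, and adjusted p = 0.35 with an estimated correlation, adjusted p = 0.0507 with the authors' fold enrichment). Immune genes had 8 higher and 8 lower of 60 (7 and 8 adjusted over the list alone). Their median was 0.24, and -0.054 after scaling on chemoreceptor genes (adjusted p = 0.0392, and adjusted p = 0.35 with an estimated correlation, adjusted p = 0.115 under quantile normalization).

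Of 4604 genes tested for both measures, 458 fell and 299 rose in both, where independent lists would share 189 and 79.4. Both measures come from the same libraries, and the TSS window can share reads with the gene model. More sharing than independent lists give is therefore built in. At 560 genes TSS density fell while gene density did not pass, and at 75 it fell while gene density rose, against 657 and 247 for independent lists. Under quantile normalization TSS calls were 648 higher and 1027 lower with a median of -0.028, and after scaling on chemoreceptor genes 162 higher and 2134 lower with a median of -0.504. Among genes whose 5' end lay at least 500 bp from another gene model, 920 passed.

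The 5' bias, the log2 ratio of TSS density to gene density, fell at 1092 and rose at 117 of 7557 genes (median -0.199). At eef-1G, eft-2 and iff-2, which serve translation, mean 4H8 density was lower at the start and higher over the gene. The elongation factor gene eef-1G fell by 3.25 ± 0.23 (adjusted p = 3.69e-08), with 4H8 TSS density going from 304 ± 77.5 to 132 ± 21.7 RPKM while gene density went from 37.7 ± 3.25 to 165 ± 49. For eft-2 (I:9163523-9166944), at -3.08 ± 0.24, TSS density went from 428 ± 43.5 to 206 ± 47.9 and gene density from 89.2 ± 8.12 to 354 ± 100. The initiation factor gene iff-2 (-2.41 ± 0.18) went from 1810 ± 117 to 863 ± 54.8 at its start and from 56.3 ± 10 to 144 ± 39.9 over the gene. Falls were -3.01 for rpl-18, -3.01 for rpl-7A, -2.75 for the poly(A)-binding protein gene pab-1, -2.60 for lias-1 and -2.59 for rpn-5, and -2.90 for chmp-7 and -2.37 for tald-1, whose models overlap ribosomal protein genes. The highest rises were at stdh-1 (2.01 ± 0.29), pst-2 (1.94), nssp-62 (1.69), sodh-2 (1.59), srab-3 (1.58), enee-1 (1.55), gei-7 (1.53), inx-7 (1.52), gasr-8 (1.50) and srg-17 (1.48). At gei-7 gene density fell by more than TSS density (-4.38 and -2.85). At stdh-1, sodh-2 and srg-17 TSS density was at most 14.3 RPKM in any library, mostly at or below input and too low to be tested, while their gene density fell (-2.46, -2.48 and -1.57).

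For 5' bias 7 lists passed camera. Ribosomal proteins had 12 lower and 0 higher of 19 (15 and 0 adjusted over the list alone). Their median was -1.06 (adjusted p = 1.11e-08, and adjusted p = 0.321 with an estimated correlation). Translation factors had 13 lower and 0 higher of 38 (16 and 0 adjusted over the list alone). Their median was -0.62 (adjusted p = 3.39e-05, and adjusted p = 0.321 with an estimated correlation). The proteasome had 11 lower and 0 higher of 27 (13 and 0 adjusted over the list alone). Their median was -0.55 (adjusted p = 0.00127, and adjusted p = 0.321 with an estimated correlation). The lid subunit gene rpn-5 and the base subunit gene rpn-2 were at -2.59 and -1.61. Ribosome biogenesis had 11 lower and 0 higher of 30 (11 and 0 adjusted over the list alone). Their median was -0.57 (adjusted p = 0.00757, and adjusted p = 0.321 with an estimated correlation). Examples were rbd-1 at -2.01 and lpd-6 at -1.83. Cell cycle genes had 13 lower and 0 higher of 52 (14 and 0 adjusted over the list alone). Their median was -0.54 (adjusted p = 0.00757, and adjusted p = 0.366 with an estimated correlation). Examples from this list, which was matched by symbol alone, were cdk-5 at -2.15 and the replication origin factor gene orc-5 at -2.09. Heat shock proteins had 13 lower and 0 higher of 42 (14 and 0 adjusted over the list alone). Their median was -0.45 (adjusted p = 0.0279, and adjusted p = 0.366 with an estimated correlation, adjusted p = 0.0612 under quantile normalization and adjusted p = 0.0639 after scaling on chemoreceptor genes). Examples were enpl-1 at -1.62, hsp-1 at -1.14 and hsp-3 at -1.07. Heterochronic genes had 1 higher and 0 lower of 8 (1 and 0 adjusted over the list alone). Their median was 0.55 (adjusted p = 0.00366, and adjusted p = 0.321 with an estimated correlation), the member that passed being lin-14 at 1.06. Aminoacyl-tRNA synthetases did not pass, with 7 lower and 0 higher of 32 (10 and 1 adjusted over the list alone) and a median of -0.44 (adjusted p = 0.183), nor did the mitochondrial ribosome, with 10 lower and 0 higher of 38 (10 and 0 adjusted over the list alone) and a median of -0.48 (adjusted p = 0.101). Under quantile normalization 267 genes were higher and 528 lower with a median of -0.011, without the S2 library of arrest 794 genes passed, and with no filter on density or a pseudocount of 1 383 and 744 passed.

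With 4H8 alone, the antibody with replicates, acs-2 and gei-7 again fell most among genes with a public symbol that moved the same way in each 4H8 pair. Gene density fell at acs-2 (-5.47 ± 0.34, adjusted p = 0.00342), gei-7 (-4.49), sodh-1 (-3.51), dap-1 (-3.36), acer-1 (-2.76), stdh-1 (-2.55), sodh-2 (-2.35), hacd-1 (-2.27), far-7 (-2.24) and the zinc finger gene unk-1 (-2.25, from 80.2 ± 0.21 to 13 ± 1.27 RPKM). It rose at asp-1 (3.34 ± 0.34, adjusted p = 0.00532), the cathepsin B family genes cpr-4 (2.78), cpr-5 (2.53) and cpr-9 (2.48), tct-1 (2.71), rps-6 (2.63), hpd-1 (2.62) and rpa-0 (2.48), which encodes an acidic ribosomal protein, and at mir-353 (3.74) and nbs-1 (2.52). TSS density rose at eft-3 (2.71, from 20.2 ± 18.8 to 138 ± 40.2 RPKM) and daf-28 (2.34) and fell at the nuclear receptor gene nhr-19 (-2.67). The 5' bias fell at rpl-18 (-3.31), eef-1G (-3.13), pab-1 (-2.96), eft-2 (-2.96), rpl-7A (-2.83) and iff-2 (-2.33) and rose at stdh-1 (2.22) and the aldehyde dehydrogenase gene alh-4 (2.04). The TSS window of alh-4 held 0 and 2.03 RPKM in the arrest libraries of 4H8, less than 3 reads, and its density went the other way with S2 (11 to 0 RPKM) and 8WG16 (33.5 to 7.13 RPKM). For gene density, 76 of 80 ribosomal protein genes were higher (79 adjusted over the list alone), and 0 after scaling on chemoreceptor genes. Their median was 1.92, and 1.40 after that scaling (adjusted p = 6.6e-35, and adjusted p = 0.835 with an estimated correlation). Chemoreceptor medians of the 4H8 replicates were 2.26 and 3.15 RPKM in arrest and 3.09 and 5.04 RPKM in recovery. Scaling on them therefore adds spread between replicates, which can end calls while the change stays large. Detoxification genes had 7 higher and 1 lower of 23 (10 and 2 adjusted over the list alone). Their median was 0.42 (adjusted p = 0.0252, and adjusted p = 0.835 with an estimated correlation). In all, camera passed 14 lists for gene density, 5 for TSS density and 5 for 5' bias, and 0 of them with an estimated correlation.

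For 4H8 alone, gene density passed at 1012 of 7240 genes (568 higher, 444 lower, median 0.056), TSS density at 971 of 6754 (256 and 715, median -0.142) and 5' bias at 431 of 7535 (45 and 386, median -0.17). With the flow-cell pair as a replicate block the counts were 2508, 1480 and 877. With no filter on density they were 149, 0 and 0 (limma, with 2369 and 1729 genes at an unadjusted p under 0.05 for TSS density and 5' bias), and with a pseudocount of 1 16 genes passed for 5' bias. Under quantile normalization they were 558 higher and 707 lower, 253 and 285, and 107 and 198. After scaling on chemoreceptor genes, gene density had 28 higher and 206 lower (median -0.375) and TSS density 13 and 372 (median -0.592). Without the first recovery library 557 genes passed for gene density, 497 for TSS density and 124 for 5' bias, and without the second recovery library 294 for TSS density and 52 for 5' bias. Without the first arrest library 260 passed for TSS density and 188 for 5' bias, and without the second arrest library 975 for 5' bias.

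The other antibodies moved in the same direction at most of the genes called with 4H8. Of 1009 such genes for gene density, 98.6% changed with the same sign with S2 and 94.7% with 8WG16, for 968 genes of TSS density 97.1% and 93.9%, and for 429 genes of 5' bias 97.9% and 94.6%. Across genes, which are not independent replicates, the mean 4H8 change correlated with that of S2 at r = 0.862 for gene density, 0.702 for TSS density and 0.559 for 5' bias, and with that of 8WG16 at 0.713, 0.577 and 0.415. The paired 4H8 changes correlated with each other at 0.808, 0.629 and 0.469. No library was shared between the sides of a single correlation, but 4H8 libraries entered all of these correlations. Without them, the S2 and 8WG16 changes correlated at 0.672 for gene density, 0.521 for TSS density and 0.37 for 5' bias. The mean 4H8 change averages both 4H8 pairs, so its correlations are not on an equal footing with those of single pairs.

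The difference between 4H8 and S2 in their response to feeding, tested with 1 S2 library per state and the spread of the 4H8 replicates, passed at 2 of 7240 genes. Both were microRNA genes with few reads, mir-84 (5.41 ± 0.34, adjusted p = 0.019) and mir-57 (-3.60 ± 0.27, adjusted p = 0.0284). The next by p did not pass, among them mir-73 (2.48, adjusted p = 0.508), nlp-34 (1.31), spig-1 (0.90) and mir-43 (-3.07, adjusted p = 0.774). Without the first or the second arrest library of 4H8 30 and 48 genes passed, and without either recovery library of 4H8 0 passed, with 107 genes at an unadjusted limma p under 0.05 in the full fit.

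Few genes passed the test for a difference in 5' bias between antibodies, which set 2 libraries against 4. Library medians over 5643 genes were 0.032 in arrest and -0.252 in recovery with 8WG16, and -0.262 and -0.488 with S2. With 4H8 they were -0.19 and -0.262 in arrest and -0.399 and -0.337 in recovery. S2 had a lower 5' bias than 4H8 at 4 genes, sto-4 (-1.73 ± 0.25, adjusted p = 0.00567), the ETS factor gene ast-1 (-1.52), the actin-binding protein gene unc-115 (-1.37) and iff-2 (-1.20), and a higher one at 0 genes (limma; 667 genes in either direction at an unadjusted p under 0.05). The nearest on the higher side were col-9 (1.33, adjusted p = 0.221) and dpf-3 (1.02, adjusted p = 0.286). Against 4H8, 8WG16 had a higher 5' bias at 26 genes and a lower one at 31 (limma; 1368 genes in either direction at an unadjusted p under 0.05). The highest were the splicing kinase gene spk-1 (1.73), mnk-1 (1.72), the chromatin factor gene lin-59 (1.72), tnt-3 (1.67), egl-45 (1.61), skr-1 (1.60), the polarity gene par-3 (1.59) and csn-5 (1.56). The lowest were ogdh-2 (-2.21 ± 0.30, adjusted p = 0.00337), rmd-2 (-1.90), row-1 (-1.87), fhip-1 (-1.68), tpst-2 (-1.64), the glutamate receptor gene nmr-2 (-1.50) and cky-1 (-1.49). In the recovery library of 8WG16 the TSS windows of ogdh-2, rmd-2, row-1, fhip-1 and nmr-2 were listed at 0 and that of tpst-2 at 3.78 RPKM, below the 11.3 RPKM of 3 reads, so these differences rest partly on a library with few or no reads. Among the highest, the 4H8 TSS windows of tnt-3, par-3 and csn-5 held at most 6.67 RPKM, and those of 8WG16 in arrest held 11, 10.5 and 11.8 RPKM, near the 8.88 RPKM of 3 reads. Under quantile normalization 10 were higher and 27 lower, and with the authors' fold enrichment 8 and 8. With a pseudocount of 1, limma called 0 genes for S2 (574 at an unadjusted p under 0.05) and 1 for 8WG16, and with no filter on density 0 for both (1143 and 2551 at an unadjusted limma p under 0.05).

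Single libraries decided these small counts. For S2 against 4H8, without the arrest or the recovery library of S2, or the second recovery library of 4H8, 0 genes passed. Without the first arrest or first recovery library of 4H8 1 gene passed, and without the arrest or recovery library of 8WG16 9 and 7. For 8WG16 against 4H8, 5 genes passed without either S2 library, 6 and 4 without the first and second arrest libraries of 4H8, 6 without either recovery library of 4H8, and 244 and 93 without the arrest and recovery libraries of 8WG16.

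The S2 library of 12 hr arrest was compared with that of 6 hr arrest. The 6 hr column carries the title of the first of 2 samples, and whether it holds both is not stated. With 1 column per time the test took its spread from the 4H8 replicates, and time coincided with flow cell, so it compares these libraries and not the times. TSS density was higher in the 12 hr library at 236 and lower at 8 of 6754 genes (median 0.22), under quantile normalization at 69 and 15 (median 0.009), and with no filter on density at 0 and 0 (limma, 1766 at an unadjusted p under 0.05). The start of rpb-7, which encodes a polymerase II subunit, went from 77.8 to 556 RPKM (2.76 ± 0.46, adjusted p = 0.000565, input 42), that of the proteasome gene rpn-5 from 7.72 to 74.9 (2.65), that of ppfr-1, encoding a phosphatase regulatory subunit, from 27 to 200 (2.68) and that of cic-1, the cyclin C gene, from 7.72 to 78.4 (2.71). Higher values were also called at swsn-6 (listed at 0 at 6 hr and at 129 RPKM at 12 hr), ccz-1 (2.94), trpp-10 (2.80), ppcd-1 (2.76), fbxa-67 (2.69) and snu-66 (2.69). Lower values were called at sdc-1 (-4.64 ± 0.91, from 324 to 8.19 RPKM, with an input of 215, but at 168 and 1.08 RPKM in the 4H8 libraries of 12 hr arrest), the copper transporter gene cua-1 (-2.74, from 59.8 to 4.68, input 51.2), cpr-4 (-2.29), moc-2 (-2.08), the fatty acid and retinol binding protein gene far-6 (-1.94) and the neuropeptide gene nlp-35 (-1.89). For gene density, limma called 0 of 7240 genes, with 500 at an unadjusted p under 0.05, and the values nearest to passing included mthf-1 (1.38, adjusted p = 0.54), pmp-5 (1.36, adjusted p = 0.54), hach-1 (1.15, adjusted p = 0.522) and col-160 (-1.09, adjusted p = 0.54). Without the second recovery library of 4H8 160 genes passed for TSS density, and without the first or second arrest library of 4H8 69 and 73 passed for gene density.

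ChIP libraries were compared with input chromatin by their enrichment and 5' bias. The number of genes with TSS density at least 3-fold over input was 813 for S2 at 6 hr, and from arrest to recovery went from 1370 to 1004 for S2, from 1281 to 741 and from 981 to 447 for the 4H8 pairs, and from 1079 to 401 for 8WG16. Over gene models the numbers were 513 for S2 at 6 hr, and went from 625 to 822 for S2, from 491 to 655 and from 477 to 382 for the 4H8 pairs, and from 354 to 323 for 8WG16. The median 5' bias over 5643 genes was -0.159 in input and -0.281 on average in ChIP. It was -0.171 ± 0.139 in 12 hr arrest and -0.369 ± 0.1 in recovery (mean ± SD over libraries, n = 4 each). The difference between ChIP and input was -0.123 (SD over the ChIP libraries 0.148), and -0.277 with a filter of 20 RPKM, for which no SD is given. These genes were chosen by their ChIP gene density, the denominator of the ratio, which can lower the 5' bias of ChIP against input. Over all genes, summed TSS density over summed gene density was 0.964 in input. It was 0.992 for S2 at 6 hr, 1.24 to 1.45 in 12 hr arrest and 1.01 to 1.03 in recovery. By this sum each 12 hr arrest library lay above input, while the mean of the median 5' bias in 12 hr arrest did not. The measures thus differ and neither was tested, so a lack of enrichment at starts over input is not shown.

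**Figure D3:**
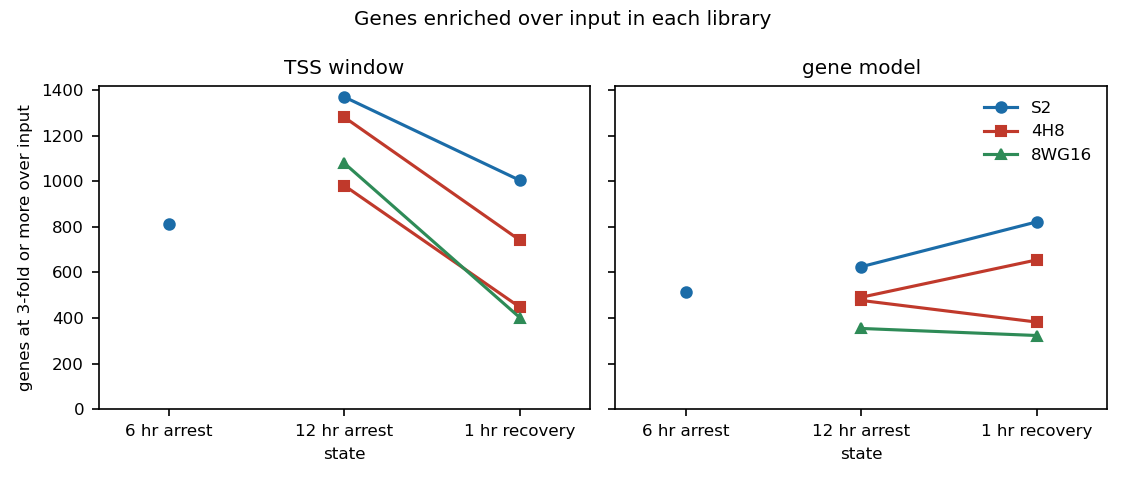
Number of genes at least 3-fold enriched over input in each ChIP library, for the TSS window and for the gene model, with lines joining the arrest and recovery libraries of a flow-cell pair. TSS counts were lower in recovery in each of the 4 pairs, for example 1370 and 1004 for S2, whereas gene model counts were higher in the S2 pair and in the first 4H8 pair and lower in the other two.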

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

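The tests of immunoprecipitation strength, of read number and of background at genes below input, the library-wide difference among genes lower in recovery, the neighbours of rising genes and of genes tested for both measures, and the splits of the libraries were chosen after the results they bear on had been seen. The neighbours of falling genes were written down before that test was run.

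A test of the difference between 4H8 and S2 in their response to feeding passed at a pair of microRNA genes. S2 had 1 library per state and took its spread from the 4H8 replicates, so the test compares these libraries, and a difference between the antibodies is not shown. At mir-84, a model of 21 bp, the difference was 5.41, with 3 reads in arrest and 0 in recovery for S2, and 0 and 0 reads in arrest and 2 and 3 in recovery for 4H8. At mir-57, a model of 23 bp, it was -3.6, with 0 and 2 reads for S2, and 3 and 4 in arrest and 2 and 3 in recovery for 4H8. Among gene models of at least 200 bp, an alternative added later, 0 genes passed.

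The counts of gene density, TSS density and 5' bias in the fit of 8 libraries were set against other splits. Of 34 splits of the libraries into 4 and 4 that could be fitted, 1 gave as many calls for each measure, the real one. It called 2743, 1956 and 1209 genes, and the highest other counts were 1, 0 and 0. Every other split puts libraries of both states on each side, so a difference between the states enters its residual and lowers its calls. These splits also ignore the flow-cell pairs, so their low counts do not exclude chance. The real split is 1 of 8 that part all 4 pairs, and the other 7 called no more than those counts, but 8 splits are too few for a share under 0.05.

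The median change in TSS density from arrest to recovery, over genes past the density filter, was -0.177 for S2, -0.14 and -0.15 for 4H8 and -0.256 for 8WG16, whereas with no filter it was 0.015 in the averaged fit. Weaker immunoprecipitation in recovery stays open in all 4 pairs, since background at chemoreceptor genes was higher in each, fewer gene models reached 3-fold enrichment in the second 4H8 pair and the 8WG16 pair (-95 and -31), and the rise by at least 164 models in the S2 pair and the first 4H8 pair may come from genes that rose on feeding. Fewer reads were argued against in both 4H8 pairs, where the recovery library had more reads and the smaller fall was still -0.14, but stay open in the S2 and 8WG16 pairs, where it had fewer and the smaller fall exceeded those of 4H8 by only -0.027. Genes called lower in recovery also differed between the arrest libraries of 4H8, first minus second, by a median of 0.38 against 0.112 to 0.166 in matched random lists, so part of the fall may follow a difference in TSS enrichment that also separates libraries of the same state. A response to feeding stays open beside it and was not tested apart from it. The 4H8 arrest libraries also entered the calls of the genes lower in recovery. The random lists were not chosen in that way, so some of the difference may be built in.

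Of the genes with higher density in recovery, 654 had a mean density below input. Median density over 1283 chemoreceptor genes, taken as background, was also higher in recovery in each pair, from 2.52 to 2.86 for S2, from 2.26 to 3.09 and from 3.15 to 5.04 for 4H8 and from 4.31 to 6.24 for 8WG16. In input the median of these chemoreceptor genes was 8.54, so a density below input need not be background. After scaling on these genes 10.4% of the 654 were still called higher. That share lies between the bounds set for a larger share of unenriched reads and against it, so background and a change on feeding cannot be told apart at these genes. The scaling was tried, and its total counts seen, before the bounds were written. It also set the 4H8 libraries of a state apart, since their chemoreceptor medians differed, and calls can end from that added spread.

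TSS density was called at 1022 genes as lower and at 177 as higher where gene density was not called the same way, of which 387 and 124 were not tested for gene density. Reads of a neighbouring gene were tested by the share with a gene called in the same direction within 500 bp, which among falls was 8.3% (85 of 1022), against 2% (90 of 4515) where TSS density was not called (Fisher's exact test, one-sided, p = 2.79e-20), and among rises it was 16.9% (30 of 177), against 3.5% (146 of 4187; Fisher's exact test, one-sided, p = 6.48e-12). Over genes tested for both measures the shares were 8.7% (55 of 635) against 2.4%, and 17% (9 of 53) against 3.9%. Neighbouring reads may account for part of these calls, as at lsm-5 beside acs-2. Neighbours that change together would give the same excess, so the test cannot tell these apart. Of the 1022 falls, 937 had no such neighbour within 500 bp, genes farther away were not counted, and no biological explanation was tested for those falls.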

How the results depend on the processing

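Scaling on chemoreceptor genes, genes far from another gene model, genes at or above the input density, the recovered reads with voom, leaving out the 8WG16 libraries and gene models of at least 200 bp were chosen after seeing the data. The averaged counts kept the commoner direction and stayed within 1.5 times under every other setting than those named here. TSS calls are limited by depth, with a median of 2 to 8 reads per window. Where not said otherwise the cause was not tested.

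In the averaged fit, gene density passed at 2740 genes under quantile normalization, with falls now the commoner direction, and at 2007 after scaling on chemoreceptor genes, again with more falls. With a filter of 20 RPKM, which tests fewer genes, 1402 passed. Averaged TSS density passed at 669 genes with no filter and at 920 far from another gene, where fewer genes are tested. Averaged 5' bias passed at 744 genes with a pseudocount of 1, 383 with no filter, 795 under quantile normalization and 509 far from another gene. Camera passed 0 lists in each averaged fit with an estimated correlation.

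For 4H8 alone, gene density passed at 149 genes with no filter, 1265 under quantile normalization, 234 after scaling on chemoreceptor genes and 1389 at or above the input density, in each case with more falls than rises, and at 1701 with the authors' fold enrichment. TSS density passed at 0 genes with no filter, 538 under quantile normalization, 385 after scaling on chemoreceptor genes and 436 far from another gene. The 5' bias passed at 16 genes with a pseudocount of 1, 660 with 20, 0 with no filter and 179 far from another gene. With the flow-cell pair as a replicate block the counts were 2508 for gene density, 1480 for TSS density and 877 for 5' bias. The block moved no averaged count by over 1.5 times (3158, 2018 and 1213).

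For S2 at 12 hr against 6 hr, gene density passed at 2 genes with a pseudocount of 1, 4 with no filter, 56 with a filter of 20 RPKM and 60 with the authors' fold enrichment. TSS density passed at 161 with a pseudocount of 20, 0 with no filter, 84 under quantile normalization and 151 with the authors' fold enrichment. For the 5' bias of S2 against 4H8 the counts were 0 with a pseudocount of 1, 9 with 20, 0 with no filter, 1 under quantile normalization, 0 with the authors' fold enrichment, 1 with gene models of any length and 0 with robust eBayes without the trend. For 8WG16 against 4H8 they were 1 with a pseudocount of 1, 243 with 20, 0 with no filter, 88 with a filter of 20 RPKM, 37 under quantile normalization, 16 with the authors' fold enrichment, 5 with any length and 11 with robust eBayes without the trend. For the difference between 4H8 and S2 in their response they were 1 with a pseudocount of 20, 13 with a filter of 20 RPKM, 1 under quantile normalization and 0 with models of at least 200 bp. The median 5' bias of ChIP minus input was -0.277 with a filter of 20 RPKM, against -0.123.

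Leaving out each library in turn gave 1765 to 2458 genes for averaged gene density, 1472 to 1893 for TSS density and 794 to 1178 for 5' bias. For 4H8 the ranges were 557 to 1404, 260 to 1092 and 52 to 975. They were 0 to 73 for S2 time and gene density, 160 to 312 for TSS density, 0 to 9 for S2 against 4H8, 4 to 244 for 8WG16 against 4H8 and 0 to 48 for the difference in response, and -0.16 to -0.098 for the median 5' bias of ChIP minus input. Among named genes, quantile normalization turned act-4 to -0.54 with 4H8 and -0.514 in the averaged fit, atp-1 to -0.395 and tba-2 to -0.003. Of the other planned values of named genes, 3266 stayed on the same side of the threshold, 137 passed it and 161 no longer did.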

Other observations

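The hypotheses at the end of this part were written before their tests were run.

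Further named genes of metabolism and the cytoskeleton, from the panel and the lists, were higher or lower on feeding or did not pass. In gene density of the averaged fit, ubq-2, which encodes ubiquitin fused to a ribosomal protein, rose by 1.80, and the methionine cycle gene sams-1 by 0.88 (0.47 after scaling on chemoreceptor genes, adjusted p = 0.369). The glyceraldehyde phosphate dehydrogenase genes gpd-2 and gpd-3 were at -0.48 and -0.54 and passed the test (adjusted p = 0.0587 and 0.0536 after that scaling, with larger falls), while the gluconeogenic gene pck-1 was at 0.21 (adjusted p = 0.33). Of the respiratory chain, ucr-2.2 and nuo-5 rose by 0.73 and 0.33 (0.37 and -0.012 after that scaling, adjusted p = 0.292 and 0.974), and the ATP synthase gene atp-2 was at 0.32 (adjusted p = 0.135). The acyltransferase gene acl-1 rose by 0.68 (0.33 after that scaling, adjusted p = 0.263) and the acetyl-CoA carboxylase gene pod-2 was at 0.18 (adjusted p = 0.562). The actin gene act-2 and the tubulin gene tba-2 rose by 0.44 and 0.45 (0.054 and 0.014 after that scaling, adjusted p = 0.906 and 0.985, and tba-2 at -0.003 under quantile normalization), and act-1 was at -0.10 (adjusted p = 0.659).

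The first hypothesis was that genes with a high 5' bias of 4H8 in arrest, where polymerase sits mostly at the start, gain gene-body density on feeding. The 10% of genes with the highest bias, 756 of 7557, had a median S2 gene density change of -0.024. Matched random lists gave 0.009 to 0.061, so these genes lay below them and the hypothesis was not borne out. Across genes, which are not independent replicates, Spearman's rho was -0.014.

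The second hypothesis was that TSS density that is higher at 12 hr than at 6 hr of arrest falls on feeding. The 236 genes called higher in the 12 hr library of S2, a call that rests on 1 column per time and ended with no filter on density, had a median 4H8 TSS density change of -1.168 on feeding, against -0.514 to -0.266 in matched random lists. Of them 158 were called lower and 4 higher with 4H8, where independent lists would share 25 that were lower. The same genes also differed between the arrest libraries of 4H8, first minus second, by a median of 0.649, against 0.125 to 0.272 in matched random lists. The fall may thus follow a difference in TSS enrichment between libraries, and a release on feeding of polymerase held at starts during longer arrest stays open beside it, since time and flow cell coincide.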
